A study of Mus musculus with 563 samples.

How the data were processed

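Single bone marrow cells were sorted into plates and sequenced with a modified Smart-seq2 protocol, per the labels' protocols, and each deposited sample is 1 cell. The authors deposited raw read counts per gene in 2 count tables with 283 and 280 cells. The submitters' processing notes list STAR 2.7.3a, Subread, featureCounts 2.0.0, DESeq2 and the mm10 build, without saying what each was used for. The deposited counts are whole numbers without molecular identifiers, and no scaling was found in them. Each table has 46078 gene entries, with 92 spike-in entries, entries for the eGFP and rat Map1lc3b transgene sequences, and counts of reads not given to a gene. Of the 372563514 and 370973373 reads, 22.3% and 25.0% lay in genes. Reads without a feature made up 34.8% and 31.5%, reads that did not align 38.7% and 38.8%, ambiguous reads 3.80% and 4.26%, and spike-in reads 0.401% and 0.465%. Gene identifiers were matched to GENCODE M21 (GRCm38) for 45143 entries, and the unmatched ones held 0.156% and 0.160% of gene reads. The 37 mitochondrially encoded genes were kept out of the totals used for scaling.

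Cells were kept with at least 50000 reads in nuclear genes, at least 1000 nuclear genes with a read and at most 20% mitochondrial reads, which left out 30 of 563 cells. The cells were sorted singly, so no doublets were called, and no clusters were made. Group and table came from the labels, with young, LO, MID and HI cells in each table. Counts were summed over the kept cells of each group and table, which gave 8 sums. Counts per nuclear gene read (CPM, per 1000000 reads) were scaled with TMM factors from edgeR 4.0.16 in R 4.3.3. Differences were taken on log2 of CPM plus 1 within each table and averaged over the tables, and the old level is the mean of LO, MID and HI. All other steps used Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.

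No label names an animal or culture, so each group was 1 sample and no test between groups was run. Sums of reads carry exact 95% Poisson intervals and shares of cells exact Clopper-Pearson intervals, which cover counting error only, since reads of 1 molecule are not independent and cells of 1 animal are not replicates. For a share of 0 the limit is that of 3 counts. Genes entered a comparison with a mean of at least 10 CPM over the groups and a read in at least 10% of kept cells. The size rule asked for a log2 difference of at least 1 in size, with the same sign and at least 0.58 in each table. It also asked for at least 20 CPM in the higher group, a read in at least 20% of its cells in each table, and no single cell with more than 20% of its reads. Unnamed gene models and pseudogenes could not meet it.

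The groups, comparisons, gene lists and size rule were fixed before the data were examined. Genes named in the text are the 12 highest and 12 lowest that met the rule in each main comparison, up to 2 highest and 2 lowest members of each list, and 15 genes always given, among them Map1lc3b, Socs3, Selp, Mki67 and Xist. Genes outside this rule are said to be chosen after their values were seen, apart from further list members given as examples. The 32 pathway lists and 10 marker lists were summarised by their median difference, beside 10000 random lists of genes drawn from 20 bins of level. Overlaps between named genes were read from the annotation. The counts of reads not given to a gene, with ambiguous reads among them, are named as HTSeq names them while the notes list featureCounts, so how reads of overlapping genes were assigned is not known. Shares of cells were taken after each cell was thinned to 100000 nuclear reads, which left 501 cells and left out 32 kept cells that had fewer.

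The steps after scaling were tested on simulated data with the real depths, levels and spread between cells. In these, 50 genes were set to each of 4 known differences. TMM factors were not used there, and no effect of animal, table or sex was simulated. The spread was drawn for each gene on its own, so genes that vary together within a cell were not simulated. Values are given over those that passed the level filter, which were all 50 except for 49 of those set to -2 in old against young. For old against young, genes set to 1, 2, -1 and -2 had median estimates of 1.01, 2.00, -0.97 and -1.96, and 42%, 88%, 26% and 69.4% of them met the size rule. For HI against LO the estimates were 0.88, 1.98, -0.94 and -1.93, and 12%, 64%, 30% and 64% met the rule. Of the genes set to no difference, 11 of 10519 and 16 of 10537 met it. These counts cover the spread of single genes between cells alone, not differences between animals or tables, nor sets of genes that vary together. A real difference of 1 was often missed by the rule, whose own bound is 1.

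Alternatives were median-ratio size factors as in DESeq2 (DESeq2 1.42.0), CPM without composition factors, pseudocounts of 0.1 and 10 CPM, and no or a stricter level filter (50 CPM and 25% of cells). Others were a mean over cells of CPM or of log2 values, no cell filter, a stricter one (200000 reads, 2000 genes, 10% mitochondrial, 410 cells) and thinned cells. Each table alone, the tables summed, and each old group alone were also used. Cells with at least 3 markers of another blood or stromal cell type (181 cells, counted without thinning) or at least 8 G2 and M phase genes (79 cells) were left out in turn, as was the deepest cell of each group and table. Added after seeing the data were runs without 1 LO cell, without 3 HI cells of each table, without cells with fewer than 10 eGFP reads, without the last 24 cells by number of each group and table, the size rule in the first table alone, MID against LO without that LO cell, and young in place of MID in the order of the groups. Spike-in reads were used only for the ratio in the closing section. Index-sort intensities are not among the deposited files and were not analysed here.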

Results

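Single hematopoietic stem cells (HSCs) were sequenced from the bone marrow of mice that carry the Gfp-Lc3 transgene, in which green fluorescent protein is joined to LC3, a protein of the autophagosome membrane. The cells came from young mice and from old mice, and the old cells were sorted into groups labelled LO, MID and HI. The labels do not say whether these names rank the brightness of the reporter or the autophagy activity, so the groups keep their label names here. The files hold 563 cells: 68 and 71 young, 72 and 72 old LO, 72 and 72 old MID, and 71 and 65 old HI cells in the first and the second of 2 count tables. Of these, 533 had at least 50000 reads in nuclear genes, at least 1000 genes and at most 20% mitochondrial reads: 63 and 71 young, 65 and 71 LO, 68 and 66 MID, and 68 and 61 HI. The median of kept cells was 271443 nuclear gene reads in young, 257238 in LO, 254723 in MID and 340529 in HI, and single cells ranged from 253 to 1064879 reads before cells were left out. Summed over kept cells the groups held 41923291, 38972543, 40419277 and 49994422 reads.

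No label ties a cell to an animal, so each group counts as 1 sample and no difference between groups was tested. Values below are reads summed over the kept cells of a group, as CPM of nuclear gene reads and as log2 differences of CPM plus 1, averaged over the 2 tables. Each bracketed pair of log2 values gives the first table and then the second. A list median is taken over the averaged differences of its genes, so it can lie outside the medians of the tables. The reads carry no molecular identifiers, so all intervals cover counting error only. A gene is said to meet the size rule when its log2 difference was at least 1 in size, had the same sign and a size of at least 0.58 in each table, and passed limits on level, on cells with a read and on reads from a single cell.

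The first comparison asks how HSCs of old mice differed from those of young mice. Several genes at the top were close to absent in young cells. Tmem215 was at 0.288 CPM in young cells and at 54.3 in old cells, a log2 difference of 5.40 (5.10 and 5.70). Osmr, the receptor subunit for oncostatin M, was at 0.320 in young and 26.9 in old cells, a difference of 4.41 (4.30 and 4.52). Mt1, a metallothionein, was higher in old cells by 4.32 (4.50 and 4.14). Ebi3, which encodes a cytokine subunit, was at 95.02 CPM in young and 12.7 in old cells, a difference of -2.83 (-2.66 and -3.00).

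Of 10721 genes above the level filter, 164 met the size rule as higher in old cells and 34 as lower. The 12 genes with the highest difference were Tmem215, Tdrd9 at 5.14, Zg16 at 5.09, Klrb1c at 4.91, Matn4 at 4.90, Sbspon at 4.45, Osmr, Rbpjl at 4.39, Mt1, Dnm3 at 4.02, Chrm3 at 3.97 and Plscr2 at 3.92. Matn4 and Rbpjl overlap on opposite strands of chromosome 2, and how reads in the shared part were assigned is not known. Tdrd9 overlaps Rd3l, and Dnm3 overlaps Dnm3os. Without the young cell numbered 35 of the first table, the difference of Plscr2 was 4.62, and no other gene among the highest or the lowest moved by a factor of 1.5 when any single cell was left out.

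Each of these 12 genes was read in a larger share of thinned cells in LO, MID and HI than in young cells. The genes were picked for their difference in the same cells, so these shares are no separate support. Tmem215 (ENSMUSG00000046593; GRCm38 chromosome 4, 40472180 to 40477168) had 12 reads in young cells (95% Poisson interval 6.20 to 20.96) and 2453 in LO, 2269 in MID and 2223 in HI cells. Cells with enough reads were also thinned to 100000 reads each, which kept 59 and 69 young, 57 and 66 LO, 65 and 62 MID, and 65 and 58 HI cells. A read of Tmem215 was then found in 2.34% of young cells (3 cells, exact interval 0.486% to 6.70%). The thinned shares were 26.8% in LO, 29.1% in MID and 36.6% in HI, and the unthinned shares 5.22%, 33.8%, 32.8% and 41.9% from young to HI. Selp (ENSMUSG00000026580; chromosome 1, 164115264 to 164150026), the adhesion molecule P-selectin, had a read in 16.4% of thinned young cells (10.5% to 23.98%; 23.1% unthinned) and in 89.4% of LO cells (82.6% to 94.3%; 88.2% unthinned). Aldh1a1 had a read in 52.3% of thinned young cells and in 99.2%, 97.6% and 98.4% of LO, MID and HI cells.

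The 12 genes with the lowest difference were Ebi3, Rnase6 at -2.40, Snx20 at -2.11, Plxdc2 at -2.07, Socs2 at -1.80, Gria3 at -1.79, Col4a2 at -1.68, Rassf4 at -1.64, Mamdc2 at -1.56, Ms4a6b at -1.54, Ablim1 at -1.52 and Kif21b at -1.43. Ebi3 (ENSMUSG00000003206; chromosome 17, 55952640 to 55957022) had 3947 reads in young cells (3825 to 4072) and 521, 586 and 506 in LO, MID and HI cells. It was read in 67.97% of thinned young cells and in 11.4%, 12.6% and 13.01% of the old groups (unthinned 71.6%, 13.97%, 13.4% and 17.8%). Col4a2 overlaps Col4a1 and Rassf4 overlaps Depp1, and how reads in the shared parts were assigned is not known. Socs2, which restrains cytokine signaling, was at 48.6 CPM in young and 13.3 in old cells.

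Genes listed beforehand as higher in old HSCs in earlier studies were higher as a group, with a median log2 difference of 1.95 (1.54 and 2.16) over 26 genes. All 26 were higher, 23 by 1.5-fold or more in each table, and 21 met the size rule. Clu was at 54.7 CPM in young and 423 in old cells, a difference of 2.99 (2.33 and 3.65). Selp was higher by 3.19 (2.35 and 4.02), Aldh1a1 by 2.45 (2.64 and 2.25) and Vwf, the von Willebrand factor of platelets, by 1.98 (1.45 and 2.51). The smallest differences were 0.53 for Cd9 and 0.81 for Zfp334.

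**Figure D1:**
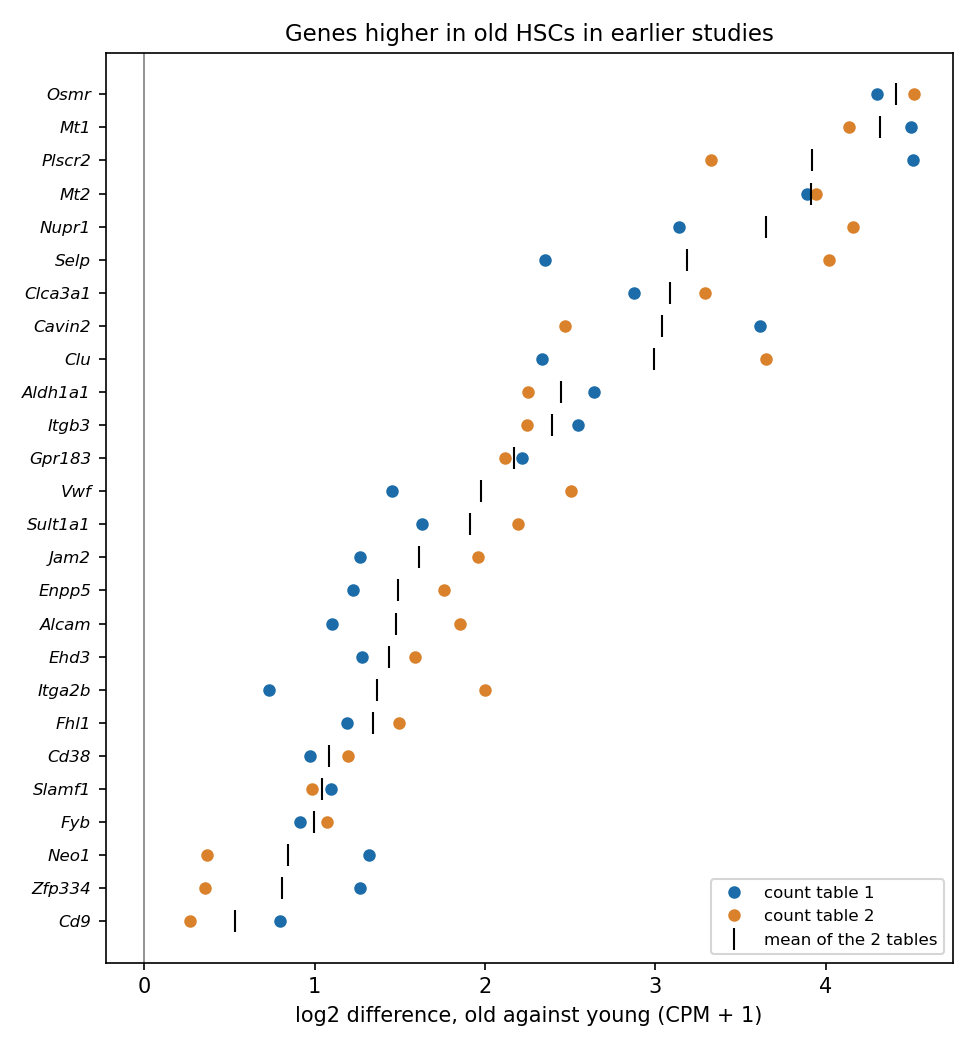
Log2 difference of old against young HSCs (CPM plus 1, horizontal axis) for the 26 listed genes, with 1 point per count table and a bar at their mean. All 26 lie above 0 in each table, from 0.53 for Cd9 to 4.41 for Osmr.

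Genes of platelets and megakaryocytes had a median of 0.73 (0.41 and 0.46), and 4 of the 17 met the size rule as higher, led by Selp and by Itgb3 at 2.39. This list shares Selp, Itgb3, Itga2b, Vwf and Cd9 with the listed ageing genes. The platelet median was 0.32 over all 22 genes without the level filter, 0.42 with the stricter filter, 0.45 as a mean of CPM per cell and 0.44 without cells read for 8 or more G2 and M phase genes. Genes of major histocompatibility complex proteins and antigen presentation had a median of 0.29 (0.40 and 0.20), and 5 of 17 met the rule. These were the class II genes H2-Eb1 at 2.67, H2-Ab1 at 1.66, H2-Aa at 1.45 and H2-DMb1 at 1.08, and Cd74, which encodes their invariant chain, at 1.73. The list of integrated stress and unfolded protein genes was at 0.21 (0.20 and 0.37), with Asns at 1.34 and Xbp1 at 0.86. Each of these medians, taken over genes that passed the level filter, lay outside the central 95% of 10000 random lists matched for level, over both tables and in each.

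Markers of multipotent progenitors had a median of -0.97 (-0.91 and -0.82) over 4 genes, with Cd34 at -1.08, Plac8 at -1.01, Flt3 at -0.93 and Cd27 at -0.15. It was -0.23 over all 8 markers without the level filter, and -0.65 without the last 24 cells by number of each group and table, a choice made after seeing the data. At least 3 of these markers were read in 46.1% of thinned young cells and in 29.3%, 29.1% and 36.6% of LO, MID and HI cells. Genes of G2 and M phase had a median of -0.35 (-0.52 and -0.26), which was 0.64 when HI cells alone stood for the old cells and 0.05 without cells that held markers of other blood cells. The 4 dendritic cell markers that passed the level filter had a median of 1.65 (1.98 and 1.30), with Cd74 and H2-Ab1 shared with the antigen presentation list, Clec9a at 1.63 and Flt3 lower. Over all 10 dendritic markers, without the level filter, the median was 0.22. At least 3 dendritic markers were read in 9.38% of thinned young cells (14.9% unthinned) and in 38.2%, 33.1% and 34.96% of LO, MID and HI cells (40.4%, 42.5% and 47.3% unthinned).

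Cytokine receptors and their regulators differed in both directions. The JAK-STAT and SOCS list had a median of 0.11 (0.30 and 0.05), outside the random lists in the first table alone. Of its members, Osmr, Socs3 and Pim2 met the rule as higher and Socs2 and Il6ra as lower. Socs3, which restrains signaling from such receptors, was at 16.4 CPM in young cells and at 113.3, 70.5 and 52.5 in LO, MID and HI cells, a difference of 2.32 (2.86 and 1.77). Among adhesion and integrin genes the median was 0.15, and 6 of 21 met the rule as higher: Selp, Itgb3, Jam2, Alcam, Itga2b and Itga6. All of these but Itga6 are also among the listed ageing genes. Among antioxidant and heme genes the median was 0.17, with Mt1, and Mt2 at 3.92, which did not meet the rule, far above Cat at -0.87. HSC identity genes had a median of 0.17, from Tek at -0.89 to Slamf1 at 1.04, while Procr was at 0.51, Hlf at -0.41 and Kit at -0.11. Interferon response genes had a median of -0.18, with Ifit1 at -1.70 and Oas2 at -1.41. NF-kB and inflammatory cytokine genes were at 0.04, from Rel at -0.88 to Il1r1 at 1.32, and immediate early genes at -0.13, from Fosb at -1.11 to Nr4a2 at 1.15.

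Genes of autophagy and metabolism were close to their young level as groups. Core autophagy genes had a median of -0.01, with Ulk2 at 0.67 and Atg10 at -0.56, autophagy receptors and mitophagy genes -0.12, and lysosome genes 0.07. Map1lc3b, the mouse gene of LC3B, was at 309 CPM in young cells and 298 in old cells, a difference of -0.05 (0.04 and -0.13). Sqstm1 was at -0.14 and Gabarap at 0.18. Glycolysis genes had a median of 0.11, with Pfkp at 0.98 and Hk2 at 0.91, and the glucose transporter Slc2a1 was at 0.08. Nuclear genes of oxidative phosphorylation were at 0.03, mitochondrially encoded genes at 0.12, the citric acid cycle and fatty acid oxidation at 0.00, the proteasome at 0.09, ribosomal proteins at 0.02 with Rps4l at -2.04, and ribosome biogenesis and Myc at 0.14. Medians were 0.10 (-0.13 and 0.22) for S phase and -0.06 (-0.23 and 0.16) for G1 regulators and quiescence, where Cdk6 was at 0.77. They were 0.16 (0.17 and -0.17) for p53 and apoptosis, 0.12 for heat shock and -0.19 for FOXO related genes. DNA methylation and chromatin genes were at -0.02 (-0.07 and 0.07) and myeloid priming at 0.13, where Prtn3 was at 1.05. Lymphoid priming was at -0.17 and erythroid genes at -0.05 (-0.20 and 0.34).

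Reads of sex linked genes differed between the young cells of the tables. All 71 kept young cells of the second table had at least 20 reads of Xist, the RNA of the inactive X chromosome, and none had more than 3 reads of the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty together. In the first table, 57 of 63 young cells had at least 20 Y-linked reads, as did most old cells of each group in each table. Xist was at 0.61 in the first table and at -8.81 in the second, so the sex linked list, with a median of 2.73 (0.19 and 5.56), follows these reads as well as age. For every gene the second table compares young cells with Xist reads and old cells that mostly held Y-linked reads, while the first compares mostly cells with Y-linked reads at each age. Under the size rule applied to the first table alone, a choice made after seeing the data, 265 genes were higher and 80 lower in old cells. These include all but 32 of the 164 and all but 6 of the 34. The main rule already asked for at least 0.58 in the first table, so much of this overlap is built in.

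Across the 10721 genes the old against young differences of the tables had a Pearson correlation of 0.419, over genes that are not independent replicates. Of 637 genes with a difference of at least 1 in the first table, 493 had the same sign in the second (77.4%). Each old group on its own differed from young cells in the listed ageing genes, with medians of 2.15 for LO, 2.01 for MID and 1.55 for HI. The antigen presentation list was at 0.40, 0.30 and 0.21 in the same order, and the G2 and M phase list at -1.43, -1.67 and 0.64.

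The second comparison asks how old cells labelled HI differed from old cells labelled LO. Genes of DNA replication and mitosis were higher in HI cells. Nuf2, a kinetochore protein, was at 8.72 CPM in LO, 19.4 in MID and 75.6 in HI cells, a log2 difference of 3.04 (1.79 and 4.29). Aurkb, the mitotic kinase Aurora B, was at 17.5 in LO and 164 in HI cells, a difference of 3.01 (2.60 and 3.41). Hells, a chromatin remodeller used in replication, was at 13.7 in LO and 72.3 in HI cells (3.17 and 1.82). Ramp2, a coreceptor for adrenomedullin, was at 62.1 in LO and 19.9 in HI cells, a difference of -1.74 (-0.97 and -2.52), and Muc1 was at 45.4 and 13.7, a difference of -1.64 (-1.99 and -1.29).

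By the size rule 170 genes were higher and 41 lower in HI than in LO cells. The 12 highest were Nuf2, Aurkb, Nsl1 at 2.92, Pkmyt1 at 2.83, Spc24 at 2.81, Dscc1 at 2.67, Espl1 at 2.58, Poc1a at 2.54, Hells, Cdk1 at 2.42, Pclaf at 2.41 and Shcbp1 at 2.37. Pkmyt1 overlaps Paqr4 and Pclaf overlaps Trip4. The LO cell numbered 58 of the first table held 81.4% of that table's LO reads in G2 and M phase genes, 14736 of 18105. Without it, a choice made after seeing the data, the difference was 4.93 for Nuf2, 4.87 for Aurkb, 3.89 for Shcbp1, 3.27 for Cdk1, 3.502 for Spc24 and 3.61 for Mki67, which was at 2.06 with all cells. Mki67, a marker of cycling cells, was at 140 CPM in LO, 92.9 in MID, 703 in HI and 343 in young cells.

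The list of G2 and M phase genes had a median of 2.04 (1.18 and 3.06) over 29 genes, of which 21 were higher by 1.5-fold or more in each table and 13 met the size rule. The median was 3.27 without the LO cell numbered 58, 1.42 without cells with markers of other types, and 1.45 without the 3 HI cells of each table with the most such reads, a choice made after seeing the data. The S phase list had a median of 1.39 (1.49 and 1.30) over 27 genes, 25 of them higher by 1.5-fold in each table and 18 meeting the rule. After thinning, at least 8 G2 and M phase genes were read in 33.3% of HI cells (41 cells, 25.1% to 42.4%) and in 5.69% of LO cells (7 cells, 2.32% to 11.4%). The share was 7.87% in MID cells (10 cells, 3.84% to 14.004%) and 14.8% in young cells (19 cells, 9.18% to 22.2%). The unthinned shares were 42.6%, 8.09%, 11.9% and 31.3%. Nuf2 (ENSMUSG00000026683; chromosome 1, 169497934 to 169531464) had 337 reads in LO (302 to 375) and 3711 in HI cells (3593 to 3832).

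**Figure D2:**
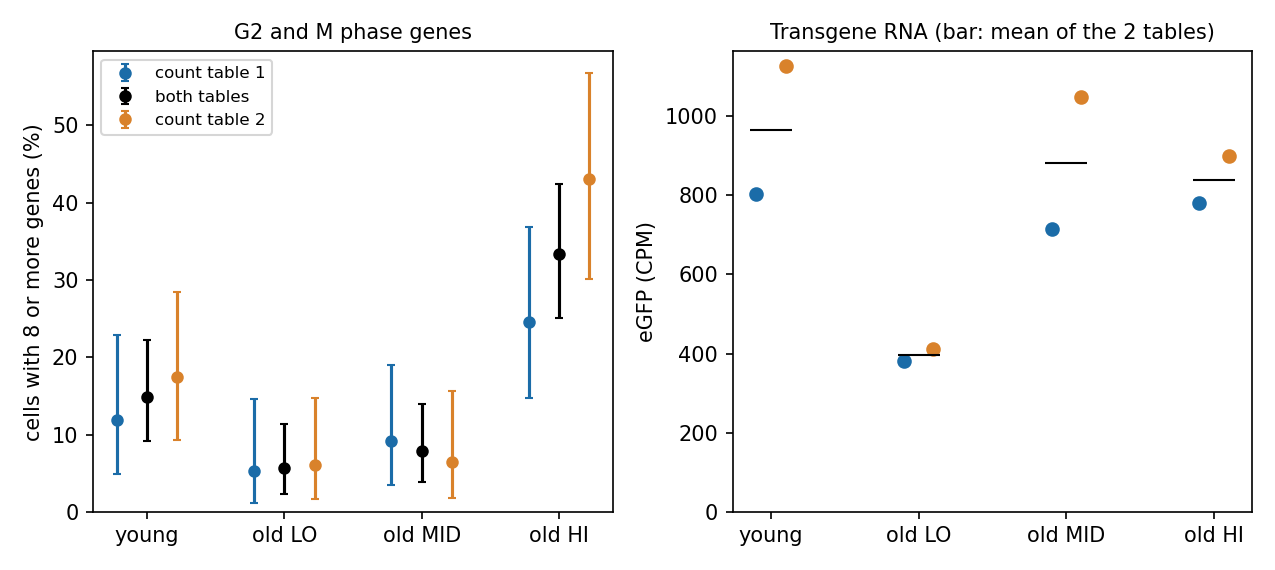
Left, percentage of cells with reads of at least 8 G2 and M phase genes after thinning to 100000 reads, by group and count table, with exact 95% intervals for counting error. Right, eGFP transgene reads in CPM by group, with 1 point per table and a bar at their mean: 33.3% of HI and 5.69% of LO cells on the left, 839 and 396 CPM on the right.

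The 12 lowest genes were Tns2 at -1.83, Ramp2, Muc1, Dnm3 at -1.57, Psd at -1.51, Runx1t1 at -1.46, Irf2bpl at -1.37, Cd200r1 at -1.36, Chd7 at -1.36, Tcp11l2 at -1.34, Kdm4a at -1.33 and Cish at -1.33. Ramp2 overlaps Vps25 and Psd overlaps Nfkb2, with the same uncertainty. Tns2 (ENSMUSG00000037003; chromosome 15, 102100413 to 102116401) had 2123 reads in LO (2034 to 2215) and 707 in HI cells (656 to 761). Genes of the ageing comparison appeared among them: 9 of the 41 were also higher in old than in young cells by the size rule, namely Amotl2, Dnm3, Ehd3, Irf2bpl, Maf, Muc1, Nr3c2, Plcl1 and Ramp2. Plxdc2 was lower in both comparisons, and Pdia5 and Top1mt were higher in both. No gene met the rule as lower in old and higher in HI cells. LO and HI cells enter both comparisons, and no value for chance that allows for this was computed.

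Nuclear genes of oxidative phosphorylation were higher in HI cells by a small amount, with a median of 0.28 (0.24 and 0.34), with 42 of 46 genes higher and Cox5a at 0.86, and proteasome genes 0.31 (0.30 and 0.38), with 29 of 31 higher. Lower lists were the listed ageing genes at -0.30 (-0.37 and -0.40, 23 of 26 lower), led by Cd38 at -1.26 and Ehd3 at -1.03, and HSC identity at -0.24 (-0.28 and -0.32, 19 of 22 lower), led by Robo4 at -0.88 and Procr at -0.79. Immediate early genes had a median of -0.38 (-0.35 and -0.51), with Zfp36 at -1.45 and Fos at -1.14, JAK-STAT and SOCS genes -0.25 (-0.39 and -0.42), with Cish and Cebpd at -1.28, and FOXO related genes -0.30 (-0.24 and -0.42). All of these lay outside the central 95% of the matched random lists, over both tables and in each. Socs3 was at -1.08 (-0.67 and -1.49), Hlf at -0.58, Selp at -0.74, Clu at -0.37, Vwf at -0.18, Kit at -0.15 and Aldh1a1 at -0.09. Xist was at 0.13 (0.59 and -0.34), and at 1.48 without the LO cell numbered 33 of the first table.

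**Figure D3:**
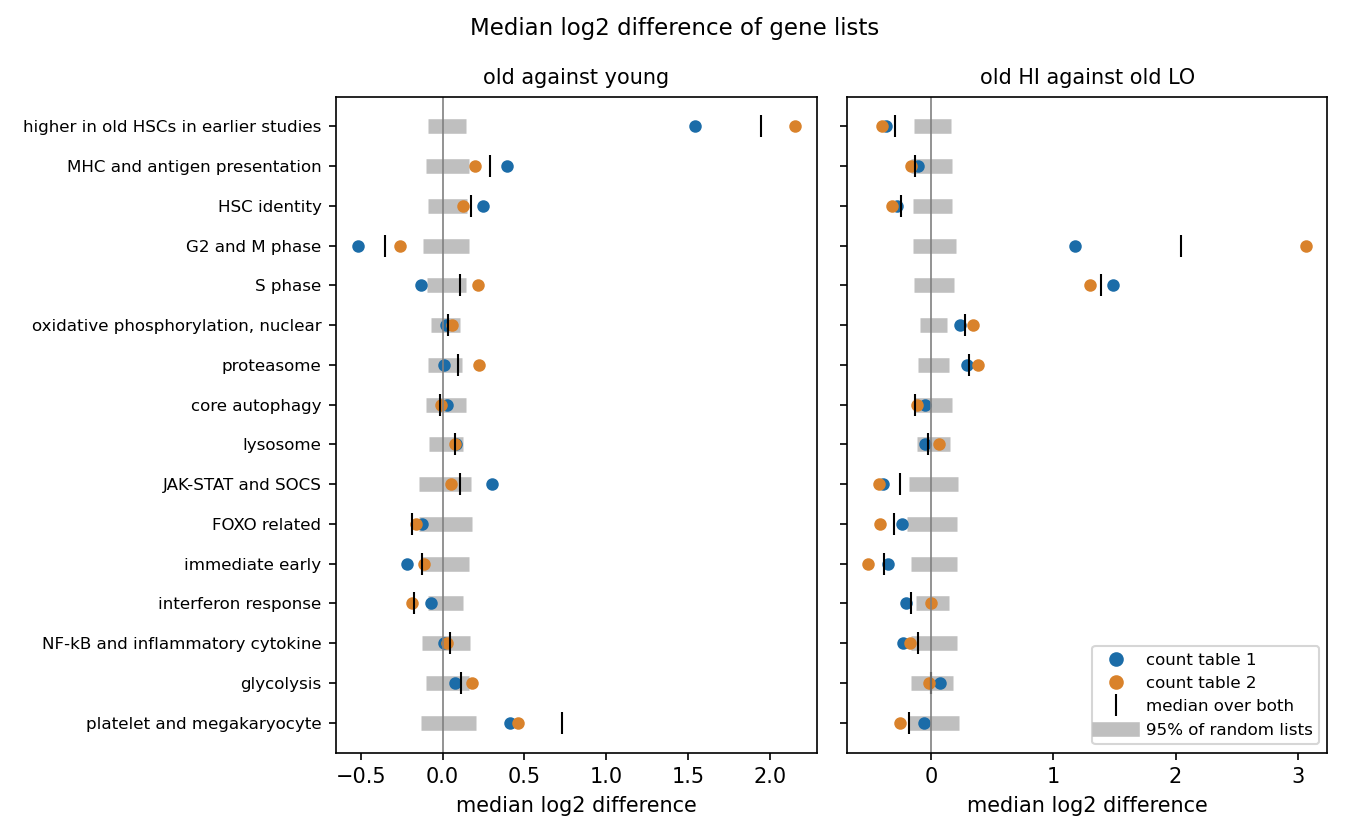
Median log2 difference of 16 gene lists for old against young (left) and HI against LO (right), with a point per count table, a bar for the median over both tables and a grey band for the central 95% of random lists matched for level. The listed ageing genes were at 1.95 on the left and -0.30 on the right, and the G2 and M phase list at -0.35 and 2.04.

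The remaining lists did not lie outside the random lists in this way. Core autophagy genes had a median of -0.13, from Gabarapl1 at -0.46 to Becn1 at 0.71, autophagy receptors -0.05 and lysosome genes -0.03. Map1lc3b was at 318 CPM in LO and 267 in HI cells, a difference of -0.25 (-0.18 and -0.32), with Sqstm1 at -0.15 and Gabarap at -0.08. Glycolysis genes were at 0.00 with Slc2a1 at -0.29, the citric acid cycle at 0.07, mitochondrially encoded genes at 0.00, ribosome biogenesis and Myc at 0.30, heat shock at 0.25, and ribosomal proteins at 0.01. Medians were -0.16 for interferon response, -0.13 for antigen presentation, -0.11 for NF-kB, 0.05 for stress and unfolded protein genes with Trib3 at -1.71, -0.11 for p53 and apoptosis, and 0.07 for antioxidant genes with Prdx4 at 1.08. They were -0.16 for adhesion, -0.18 for platelet genes, 0.16 for G1 regulators with Cdk6 at 0.47, and -0.11 for myeloid genes. Lymphoid genes were at 0.13 (-0.14 and -0.15), opposite in sign to each table alone. Erythroid genes were at 0.40 (-0.06 and 0.69). DNA methylation and chromatin genes had a median of -0.03 with members that met the rule in both directions: Ezh2 at 1.54 and Dnmt1 at 1.05 were higher, and Ezh1 at -1.05 lower.

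When cells with at least 8 G2 and M phase genes were left out of every group, 76 genes were higher by the rule, of which 61 were among the 170. The S phase median was then 1.25 over 24 genes, oxidative phosphorylation 0.15, the proteasome 0.23, the listed ageing genes -0.27 and HSC identity -0.17. The G2 and M phase median was -0.03 over the 6 genes left above the level filter, a value that leaving out these cells sets by construction.

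The transgene itself was read in the libraries. The eGFP sequence was at 964 CPM in young, 396 in LO, 881 in MID and 839 in HI cells, and the rat Map1lc3b sequence at 862, 366, 806 and 800. Between HI and LO cells eGFP differed by 1.08 (1.03 and 1.13) and rat Map1lc3b by 1.12 (1.05 and 1.20). Among kept LO cells, 9 of 65 in the first table and 1 of 71 in the second had no eGFP read, and among kept MID cells 1 of 68 and 2 of 66. In young and HI cells every kept cell had at least 1.

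Across the 10721 genes the HI against LO differences of the tables had a Pearson correlation of 0.364. Of 856 genes with a difference of at least 1 in the first table, 640 had the same sign in the second (74.8%). More genes were read per HI cell: after thinning the median was 6364 genes in young, 6666 in LO, 6577 in MID and 7188 in HI cells, and without thinning 7483, 7674, 7934.5 and 8848.

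The third comparison asks whether MID cells lay between LO and HI cells. Of the 211 genes that met the size rule between HI and LO, 58.3% had a MID value between the others in each table. These genes were chosen because LO and HI lay apart, and no value for unordered groups was computed, so the share does not answer the question. Young cells lay between for 63.03% of the same genes, a value added after seeing the data. S phase genes had medians of 0.52 for MID against LO and 0.82 for HI against MID. G2 and M phase genes were at -0.14 for MID against LO (-0.41 and -0.003) and at 2.23 for HI against MID. Without the LO cell numbered 58 of the first table, MID against LO was 0.96 (2.38 and -0.01) for these genes and 1.72 for Aurkb, which was at -0.10 with it. The thinned shares of cells with at least 8 of the genes were 5.69% in LO, 7.87% in MID and 33.3% in HI, and the intervals of LO and MID overlapped. Only 9 genes were higher and 4 lower by the rule in MID than in LO cells, against 110 higher and 21 lower in HI than in MID cells. Across genes, the difference of HI against LO in one table had a correlation of -0.105 and -0.179 with the difference of MID against young in the other table, and of -0.139 and -0.151 within a table.

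Markers of other blood and stromal cells were read in parts of each group, beside the dendritic markers above. At least 3 markers were read, after thinning, in 3.91%, 13.01%, 11.8% and 18.7% of young, LO, MID and HI cells for megakaryocytes and platelets, which share genes with HSCs. The shares were 0.781%, 3.25%, 3.94% and 5.69% for monocytes and macrophages, and 3.91%, 0.813%, 3.94% and 3.25% for erythroid cells. For T and NK cells they were 0% (which allows up to 2.34%), 2.44%, 2.36% and 4.07%, and for endothelial and stromal cells 3.91%, 4.88%, 0.787% and 1.63%. Without thinning, the shares from young to HI were 10.4%, 16.9%, 14.2% and 24.03% for megakaryocytes and platelets, and 8.96%, 9.56%, 11.2% and 17.1% for monocytes and macrophages. They were 9.70%, 2.94%, 8.21% and 11.6% for erythroid cells, 3.73%, 7.35%, 7.46% and 8.53% for T and NK cells, and 11.9%, 16.2%, 9.70% and 10.1% for endothelial and stromal cells. In thinned cells neutrophil markers gave 0.813% in LO, 0.787% in MID and 0% in young and HI cells, and markers of B cells and of mast cells and basophils gave 0% in every group. Without thinning the shares were at most 2.24% for neutrophil and 3.10% for B cell markers, and 0% for mast cells and basophils. Counted without thinning, 181 of the 533 kept cells had at least 3 markers of another type, with dendritic cells, megakaryocytes and multipotent progenitors not counted.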

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

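The tests on the cell cycle and the transgene below were chosen only after the results were seen, apart from the thinned shares of cells, which were planned. Spike-in RNAs, added in the laboratory, were not used in the comparisons. They are given here because the medians of the old groups over all kept cells lay above that of the young cells, which served as control. The median number of gene reads per spike-in read was 40.9 in young, 44.95 in LO, 48.2 in MID and 76.9 in HI cells. The quartiles were 28.9 and 96.4 in young, 32.9 and 101.1 in LO, 34.8 and 99.1 in MID, and 43.9 and 131.5 in HI cells. In the first table the medians were 36.9, 43.4, 44.1 and 58.9, and in the second 41.9, 46.5, 48.7 and 84.4. Among cells read for fewer than 8 G2 and M phase genes they were 37.5, 43.7, 45.1 and 56.01. The last 24 cells by number of each group and table had higher ratios than the earlier ones, with 116.99 against 37.7 in LO and 153.7 against 53.9 in HI, and no label names a difference between these cells.

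Genes of G2 and M phase, which serve chromosome segregation, were higher in HI than in LO cells, with a median log2 difference of 2.04. Deeper libraries of the HI cells, in number of reads, do not account for it, since 33.3% of HI cells had at least 8 of the genes after thinning to the same number of nuclear reads, with a lower bound of 25.1% above the upper bound of 11.4% in LO. A few HI cells with very many such reads do not account for it either, as the median was 1.45 without 3 such cells of each table. Leaving out the last 24 cells by number, which hold fewer spike-in reads, gave 3.30, close to the 3.27 without the LO cell numbered 58 alone, which is among them, and in the earlier cells the thinned shares were 34.2% in HI (23.9% to 45.7%) and 6.49% in LO (2.14% to 14.5%). What stays open, untested, is a difference that the sort made between the groups, a difference between animals, and a higher RNA content of HI cells, which had 7188 genes against 6666 in LO after thinning.

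Reads of the transgene were lower in LO than in HI cells, by a log2 difference of 1.08 for eGFP. LO cells with almost no transgene reads are part of it, with 27 kept LO cells under 10 eGFP reads among 37 such cells in all, yet the difference was 0.87 without them. Reads shared with the mouse Map1lc3b gene cannot give the 1.08, as eGFP has no counterpart in the mouse genome, and mouse Map1lc3b itself was at -0.25. A sort that follows transgene RNA over all 3 groups may account for LO, but HI against MID was at -0.048 (0.13 and -0.22 in the tables), so this is left open by tables that go opposite ways. Differences between animals, such as in transgene copies, also stay open and were not tested.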

How the results depend on the processing

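Settings chosen after seeing the data were those without 1 LO cell, without 3 HI cells, without cells with few eGFP reads, without the last 24 cells by number, the first table alone for the size rule, MID against LO without 1 LO cell, and young in place of MID in the order of the groups. No paired analysis was possible because replicate numbers name single cells and no result comes from a test. The main differences were already taken within each count table. Where no reason is given below, the cause was not tested.

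The listed ageing genes, at 1.95 in old against young, were at 1.499 with a pseudocount of 10 CPM, 2.54 as a mean over cells of log2 values, 2.24 without cells with markers of other types, 1.54 in the first table and 1.55 with HI as the old cells, and stayed above 0 in every setting tried. The G2 and M phase list of old against young turned from -0.35 to 0.054 without cells with markers of other types and to 0.64 with HI as the old cells.

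The size rule in old against young was met by 164 genes as higher and 34 as lower. With a pseudocount of 10 CPM, which shrinks differences by construction, the higher count was 63.4% of the 164 and 21 genes were lower. The stricter level filter, which leaves fewer genes, gave 66 higher (40.2% of the 164) and 11 lower. With MID as the old cells the higher count was 62.8% of the 164. The lower count was 58 without cells with markers of other types, 58 without the last 24 cells, 58 with LO and 76 with HI as the old cells. The first table alone gave 265 higher (161.6% of the 164) and 80 lower, where only 1 table has to pass.

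In HI against LO the S phase list, at 1.39, was at 1.91 as a mean of log2 values, 0.82 for HI against MID and 0.52 for MID against LO. The G2 and M phase list, at 2.04, was at 1.65 with a pseudocount of 10 CPM, 2.57 as a mean of CPM per cell, 1.69 as a mean of log2 values, 1.42 without cells with markers of other types and 2.45 in thinned cells. It was 3.19 without the deepest cell of each group and table, 3.27 without the LO cell numbered 58, 1.45 without 3 HI cells of each table, 3.30 without the last 24 cells, and 1.18 and 3.06 in each table. It turned to -0.034, over 6 genes, without cells read for 8 or more of its genes, by construction, and to -0.14 for MID against LO, as did Aurkb at -0.10 and Tacc3 at -0.10. The MID against LO reversals rest on the LO cell numbered 58 of the first table: without it the G2 and M phase list was at 0.96 (2.38 and -0.008 in the tables), Aurkb at 1.72 and Tacc3 at 0.25, while the S phase list, at 0.497, hardly moved.

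The HI against LO counts (170 higher, 41 lower) were 72 and 16 with the stricter level filter, 110 and 21 for HI against MID, and 9 and 4 for MID against LO (9 and 5 without the LO cell). There were 76 higher without cells read for 8 or more G2 and M phase genes, 19 lower with a pseudocount of 10 CPM and 83 lower without the last 24 cells. Shares of cells with at least 8 G2 and M phase genes became 31.3% in young and 42.6% in HI cells without thinning. With at least 5 genes they were 38.3%, 13.01%, 18.9% and 45.5% from young to HI.

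Of all list medians under the alternatives, 786 moved by less than the spread between tables, 70 by more and 2 reversed in old against young, and 810, 46 and 2 in HI against LO. For single genes the counts were 5835, 533 and 0, and 5733, 633 and 2. These reversals do not cover every change of sign. The p53 and apoptosis list of old against young, at 0.16, was at -0.17 in the second table. Lymphoid priming in HI against LO, at 0.13, was at -0.14 and -0.15 in the tables. Xist in old against young also changed sign in the first table. Scaling by size factors or without factors left the median of all genes between 0.00 and 0.02. Genes under a mean of 10 CPM were left out by a chosen filter, except in the setting without it. Thinned shares left out cells under 100000 reads.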

Other observations

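The genes of the first paragraphs were chosen after their values were seen, and the tests of the Xist pattern were chosen only after that result was seen, apart from the genes that escape X inactivation, whose bounds were set before their values were seen. Some genes known from epithelial cells and cell junctions met the size rule as higher in old HSCs, but no list of such genes was fixed, so nothing is said of them as a group. The claudin gene Cldn5 was at 28.9 CPM in young and 192 in old cells, a log2 difference of 2.69 (2.79 and 2.58). Tm4sf1 was higher by 3.65, Epcam by 1.84, Lsr by 1.67, Podxl by 1.51 and Marveld2 by 1.09, and each of these met the size rule, while the junction genes F11r at 0.08 and Ocln at 0.17 did not. Among nuclear receptors, Rorb was higher by 2.79, Pgr, the progesterone receptor, by 1.96 and Nr3c2, the mineralocorticoid receptor, by 1.23, while Nr3c1, the glucocorticoid receptor, was at 0.10. Of the Gimap genes, Gimap6 was at 647 CPM in young and 256 in old cells, a difference of -1.33. Gimap8 at -1.14 also met the rule as lower, and the other members above the level filter, Gimap9 at -0.50, Gimap1 at -0.49 and Gimap5 at -0.32, did not. Gimap1os, a transcript named for the strand opposite Gimap1 and not a member, met it as lower at -1.10.

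Between HI and LO cells, single genes of DNA synthesis and repair outside the fixed lists were among those that met the size rule, picked for that reason and not as a group. The polymerase and primase genes Pola1, Prim1 and Prim2 were at 1.26, 1.47 and 1.58, and the ligase gene Lig1 was at 1.54. Brca2, used in the repair of double-strand breaks, was at 28.2 CPM in LO, 37.95 in MID and 91.8 in HI cells, a difference of 1.68 (1.98 and 1.38). Chek1, a checkpoint kinase, was higher by 2.28, Bard1 by 1.79 and Exo1 by 1.71. Among genes lower in HI cells were those of the receptors S1pr1 at -1.28 and Ptger4 at -1.16, and those of the transcription factors Maf at -1.24 and Rora at -1.12. Each of these met the size rule.

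All 71 kept young cells of the second table held at least 20 reads of Xist. An exchange of labels with a group of old cells would leave old cells of this kind, and among 399 kept old cells only 1 held Xist reads with fewer than 20 Y-linked reads. RNA of other cells mixed into the wells would put Xist and Y-linked reads together, which was so in 0 of the 71 young cells and in 10 old cells. Young cells of female animals in the second table would raise genes that escape X inactivation by a median log2 of at least 0.3 over the first table, beyond old cells, but the median was -0.25, which met the bound of 0.1 set against it. Kdm6a at 1.18, Kdm5c at -0.25 and Ddx3x at -0.45 went opposite ways, by more than the distance to that bound. That condition was added after the values were seen. The prediction was not met, but genes that disagree this much cannot decide the sex of the animals, which no label gives (Eif2s3x was below the level filter). The reads themselves, with at least 29 of Xist and at most 3 Y-linked in each of the 71 cells, are what female cells would give. They argue against male cells in this group, as the medians of Y-linked reads were 67 to 97 in every other group and table. In every other group and table the median cell had 0 Xist reads.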
